A study of Mus musculus with 6 samples.

How the data were processed

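The series holds 6 samples of CD4+YFP+ T cells sorted by flow cytometry from lymph nodes of mice that carry a Foxp3-driven fusion of GFP and Cre, a YFP reporter in ROSA26 and either 1 (Het) or 2 (KO) lox copies of Dicer. Total RNA was extracted with TRIzol and amplified and biotin-labelled with the MessageAmp II kit, per the labels' protocols. The values used are the probe set intensities that the authors deposited, normalized with GCRMA per the labels. GCRMA subtracts a background estimated from probe sequence, normalizes between arrays and summarises the probes of a probe set, and its software version is not given in the sources used here. The intensities are on a linear scale, judged from their range of 1.23 to 170023, so log2 was taken first. Such background subtraction pushes dim probe sets toward a floor, which enlarges the folds of genes that are dim in one group.

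Of 45101 probe sets, 64 control probe sets and 1 with missing values were left out, and the 29507 with a log2 value above 4 on at least 3 of the 6 arrays were tested. Gene names came from the platform's annotation table: of all 45101 probe sets 34958 had 1 gene symbol, 932 had several and 9211 are unnamed here. Of those with 1 symbol, 34754 matched a mouse reference gene table (GRCm38.p6) by gene identifier, with 0 symbols changed. Among tested probe sets 23976 had 1 symbol, 685 several and 4846 none, and 13280 genes were measured. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it, and probe sets of opposite sign are given beside it for the genes named by the rule below. List counts use that probe set, and the list members Ago2, Il2rb and Ighm had other probe sets past the threshold. No gene was named from a probe set with several symbols.

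KO was compared with Het by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, no covariates) with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Differences are KO minus Het on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists with at least 3 measured members, and again with an estimated correlation and with fry. Control ratios were compared by an exact permutation test and genes near Dicer1 by Fisher's exact test. For 25 measured genes the reference table held no position. Plots were drawn with matplotlib.

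The tests, the 28 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Dicer1, Foxp3 and Cd4, the 10 genes higher and 10 lower with the largest log2 difference among those past the threshold with non-overlapping groups (predicted genes and clone names passed over), and from each list up to 4 members past the threshold by smallest p, or 2 as values where 0 passed. A few further members of the lists, the markers of other cell types, and the genes at the end of the text were named after their values were seen. The lists cover regulatory T cell genes, suppressor molecules, naive and conventional T cell genes, activation, Th1, Th2, Th17 and follicular helper genes, cytotoxic effectors, chemokine receptors and homing, proliferation, type I interferon and interferon gamma responses, IL-2 and STAT5, apoptosis and p53, glycolysis, cholesterol synthesis, reported microRNA targets and the Dicer pathway. They also cover markers of B cells, plasma cells, myeloid cells, CD8 T cells, NK cells, gamma delta T cells, erythroid cells, stroma and alpha beta T cells. Some genes stand in more than 1 list.

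The steps were tested on simulated data with 29507 probe sets and the spread of these arrays. Of these probe sets 200 were changed, 50 by each size, which is fewer than the 525 called in the data. The share recovered depends on how many change, so it may differ in the data. In 20 simulations the comparison recovered 1.6% of probe sets changed by a log2 of 0.5, 48.1% of those changed by 1, 81.2% by 2 and 92.4% by 3, and 5.37% of its calls were false. With no change the median number of calls was 0. Here too the probe sets were simulated as independent, so these rates may not hold for arrays whose genes vary together. A list shifted by 0.5 was called in 100% of simulations and unshifted lists in 0.5% of tests, on 13280 genes simulated as independent. Alternatives tried were a block on the replicate letter, other filters, quantile normalization, median centring, an intensity trend with robust estimation, array weights, the mean of a gene's probe sets, other windows near Dicer1 and leaving out each array. After the data were seen, fits without both B arrays and with the beta-actin ratio as a covariate were added. A search for microRNA seed matches was not run, since no transcript sequences were used here.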

Results

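RNA of CD4+YFP+ T cells from mouse lymph nodes was profiled on 6 expression arrays, 3 from Dicer wt/lox mice (Het) and 3 from Dicer lox/lox mice (KO). In both genotypes Cre was produced under the control of Foxp3, the gene of the lineage factor of regulatory T cells. The ROSA26 reporter switches YFP on in any cell in which Cre has acted, so YFP marks cells that have expressed Foxp3. Dicer, the enzyme that cuts microRNA precursors into mature microRNAs, is the target of Cre in these cells, and the comparison of KO with Het asks how their messenger RNAs differ without it. The 3 arrays of a group carry the letters A, B and C, and the labels do not say that they are separate animals, so the p-values measure only the spread between these samples, which may be technical. Median intensities were 58.1 to 61.5 per array, Pearson's r across probe sets was 0.977 to 0.986 within a group and 0.960 to 0.979 between groups, and 3 arrays per group limit the precision.

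The deleted gene and the gene that marks the cells were measured first. The probe set that stands for Dicer1 read 1113 ± 78.5 (SD, n = 3) in Het and 1090 ± 85.1 in KO, a log2 difference of -0.03 ± 0.10 (SE; limma, adjusted p = 0.891) that was 0.03 without Het A and 0.01 without KO A. The other Dicer1 probe set read 1218, 1120 and 1345 on the Het arrays and 897, 976 and 709 on the KO arrays, a log2 difference of -0.52 ± 0.15 with adjusted p = 0.145. Foxp3 read 9960, 8945 and 9769 in Het A, B and C and 5453, 9417 and 5420 in KO A, B and C, a log2 difference of -0.55 ± 0.23 that did not pass the test (adjusted p = 0.285). Cd4, the coreceptor used to sort the cells, read 5227 ± 559 in Het and 5703 ± 824 in KO (log2 0.12, adjusted p = 0.692), and its dimmer probe set gave log2 -0.03. Where the Dicer1 probes lie relative to the deleted part is not known here, so these values do not check the genotype labels.

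In KO cells the granzyme genes Gzma, Gzmb and Gzmk, the Th1 genes Ifng and Tbx21 and 11 of 19 interferon gamma response genes were higher, and Cd83, Tox, Pdcd1 and Nrp1 were lower. None of the list calls by camera held with an estimated correlation (smallest adjusted p = 0.298). Among 29507 probe sets tested, 525 changed at an adjusted p under 0.05 (limma), 328 of them higher and 197 lower in KO, and 306 changed by a log2 difference of at least 1 (207 higher, 99 lower). By 1 probe set per gene, 182 genes were higher and 127 lower. All 525 had every KO array on one side of every Het array. That separation held for 26.2% of all probe sets tested, against 10% by chance. The 525 calls rest on all 6 arrays: 3 probe sets were called without Het A, 18 without Het B, 2 without Het C, 176 without KO A, 8 without KO B and 0 without KO C (limma; 4227 at an unadjusted p under 0.05). Without both B arrays, which had higher B cell and CD8 T cell markers than the other arrays of their group, limma called 0 (5274 at an unadjusted p under 0.05). The median absolute log2 difference of the 525 was then 1.12, against 1.14 with all arrays. The 525 were called on all 6 arrays and their groups do not overlap, so a large median there is not separate support.

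The 10 named genes with the largest increases began with Gzma, which encodes granzyme A, at 10.6, 17.2 and 26.4 in Het and 959, 6859 and 20718 in KO (log2 8.25 ± 1.13, SE; limma, adjusted p = 0.0394). Tgm2, a transglutaminase, rose from 35.1 ± 8.47 to 4950 ± 3460 (SD, n = 3; log2 6.95), and Enah, an actin regulator, from 39.6 ± 22.5 to 2245 ± 1270 (log2 5.77). Of the 5 Tgm2 probe sets 4 passed, and the remaining one read 137 in Het and 190 in KO (log2 0.43; limma, adjusted p = 0.383). Igkv9-120, an antibody light chain segment, rose by a log2 of 5.62, Gzmk, a granzyme, by 4.83, Plac8 by 4.73 and Mpeg1, the gene of perforin-2, by 4.61. The other Igkv9-120 probe set gave log2 1.03 (limma, adjusted p = 0.22). Ermn (4.50), Ifitm1, an interferon-induced membrane protein (4.27), and Sv2c, a synaptic vesicle protein (4.18), completed the 10, with adjusted p between 0.0170 and 0.0485 for all of them. On each Het array Gzma, Tgm2, Igkv9-120, Gzmk, Ermn and Sv2c lay below the median of all probe sets, so the size of their folds depends on the GCRMA background step.

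Among the 10 named genes with the largest decreases, Npas4, an activity-induced transcription factor, fell from 408 ± 187 in Het to 14.6 ± 3.20 in KO (SD, n = 3; log2 -4.69 ± 0.43, SE; limma, adjusted p = 0.0222). Iftap fell from 502 ± 176 to 26.1 ± 9.82 (log2 -4.29) on its brighter probe set, while its other probe set gave log2 0.21 at intensities near 20. Dmd, the gene of dystrophin (log2 -3.78), Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase (-3.52), and Hdac9, a histone deacetylase (-3.47), fell too. A dimmer Gucy1a1 probe set gave log2 -0.14. Tktl1 (-2.42), Slc9b2 (-2.39), Mcoln3, a lysosomal ion channel (-2.28), Gprasp2 (-2.22) and Zfp647 (-2.20) were also lower. Mcoln3 passed most narrowly, at adjusted p = 0.0489, and its dimmer probe set gave log2 -0.38. On each KO array 8 of these 10 genes, all but Gucy1a1 and Mcoln3, lay below the median of all probe sets.

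**Figure D1:**
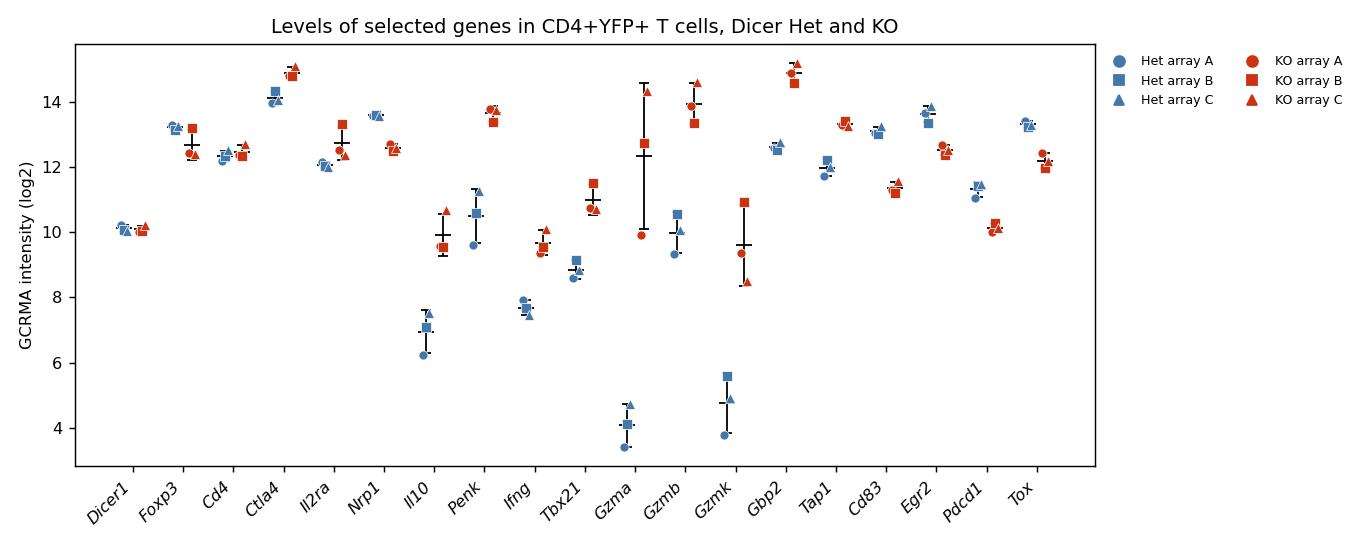
GCRMA intensity (log2, vertical axis) of 19 genes on each of the 6 arrays. Points are arrays (Het blue, KO red, shape by letter), and bars are the mean ± SD of the 3 arrays of a group. Gzma, Gzmb, Il10 and Gbp2 lie higher on every KO array than on any Het array, Cd83, Tox, Pdcd1 and Nrp1 lie lower, and Dicer1 on the probe set drawn and Cd4 overlap between the groups.

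Regulatory T cell genes moved both ways. Of 30 measured members, 2 rose, 1 fell and 27 did not pass (4 higher and 1 lower when adjusted over the list alone). Penk, the precursor of enkephalin peptides, rose 8.91-fold, from 1590 ± 833 to 12880 ± 1920 (SD, n = 3; limma, adjusted p = 0.0364). Il10, an anti-inflammatory cytokine, rose 7.89-fold (adjusted p = 0.0462), while Nrp1, a surface receptor of thymus-derived regulatory T cells, fell from 12230 ± 163 to 6161 ± 447 (log2 -0.99 ± 0.08, adjusted p = 0.0191) on all 4 of its probe sets. Ctla4 (log2 0.76, adjusted p = 0.069), Il2ra (0.67), Ikzf2 (-0.24) and Tnfrsf18 (0.20) did not pass. The list as a whole lay higher than other genes by camera (median log2 0.33, adjusted p = 0.00245), but not with an estimated correlation (adjusted p = 0.329). Suppressor molecules, a list that shares 6 measured genes with this one (Il10, Ebi3, Fgl2, Ctla4, Entpd1 and Nt5e), had 13 measured members, so the 2 list tests are not separate. Il10 and Gzmb rose, Pdcd1, the inhibitory receptor PD-1, fell from 2570 ± 396 to 1128 ± 108 (log2 -1.18, adjusted p = 0.0302), and 10 did not pass (5 higher and 2 lower when adjusted over the list alone). The median log2 was 0.86 (camera, adjusted p = 0.00369), with adjusted p = 0.329 with an estimated correlation.

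Among genes of Th1 cells and of cytotoxic granules, 6 rose and 0 fell. Ifng, the gene of interferon gamma, rose from 206 ± 33.0 in Het to 839 ± 233 in KO (SD, n = 3; limma, adjusted p = 0.0263). Tbx21, the gene of the Th1 factor T-bet, rose 4.38-fold (467 ± 91.5 to 2097 ± 717, adjusted p = 0.0317), and Runx3, a factor of Th1 and cytotoxic cells, 2.37-fold on its brighter probe set (adjusted p = 0.0232). These were the 3 of 16 measured Th1 genes that passed. When adjusted over the list alone 10 rose and 0 fell. The median log2 of the list was 1.30 (camera, adjusted p = 8.7e-07), with adjusted p = 0.298 with an estimated correlation. Of 18 cytotoxic effector genes, Gzma, Gzmb and Gzmk rose and 15 did not pass (6 higher and 0 lower when adjusted over the list alone). Gzmb read 1072 ± 434 in Het and 16750 ± 7390 in KO, a 15.6-fold difference (adjusted p = 0.0253). Eomes (log2 2.93, adjusted p = 0.10) and Prf1, the gene of perforin (0.86, adjusted p = 0.29), did not pass. The median log2 was 1.05 (camera, adjusted p = 6.09e-06), with adjusted p = 0.310 with an estimated correlation. The CD8 T cell gene Cd8a read 223, 860 and 267 in Het and 206, 1301 and 203 in KO on its brightest probe set, so in KO A and KO C, which hold the granzyme increases too, Cd8a lay below Het B.

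The other helper programmes did not pass camera. Of 12 Th2 genes 0 passed (limma; 3 higher and 0 lower at an unadjusted p under 0.05, and 3 higher when adjusted over the list alone). Il4 read 18.1 ± 4.88 in Het and 239 ± 137 in KO (SD, n = 3; log2 3.52, adjusted p = 0.0541) and Nfil3 gave log2 1.65 (adjusted p = 0.0909), with camera's adjusted p = 0.130 for the list. Of 11 Th17 genes 0 passed (5 higher and 2 lower at an unadjusted p under 0.05, 1 higher when adjusted over the list alone). Stat3 gave log2 0.62 (adjusted p = 0.0587), Il21 1.56 (adjusted p = 0.145) and Il17a 0.15 (adjusted p = 0.56). Camera's adjusted p for the Th17 genes was 0.0918, or 0.0208 without Het B. Among 15 follicular helper genes Pdcd1 and Tox, a nuclear factor of T cell development, fell and 13 did not pass (4 higher and 4 lower when adjusted over the list alone). Tox went from 10130 ± 679 to 4701 ± 765 (log2 -1.12, adjusted p = 0.0302). The follicular helper list had a positive median (0.14) and a negative direction by fry, neither past the test (camera, adjusted p = 0.889).

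T cell activation genes moved in both directions. Id2, an inhibitor of E protein transcription factors, rose 2.60-fold (12100 ± 1470 to 31320 ± 1220, SD, n = 3; limma, adjusted p = 0.0191). Cd83, an activation marker, fell from 8795 ± 842 to 2629 ± 347 (log2 -1.75 ± 0.13, SE, adjusted p = 0.0191). Egr2 (log2 -1.11, adjusted p = 0.0424) and Egr3 (-0.64, adjusted p = 0.0373), transcription factors induced by antigen receptor signals, also fell. The other 22 of 26 members did not pass (9 higher and 4 lower when adjusted over the list alone). Camera's adjusted p was 0.115, or 0.0254 without KO B, at a median of 0.38. Of 25 naive and conventional T cell genes 0 passed (limma; 8 higher and 1 lower at an unadjusted p under 0.05, 3 higher and 1 lower when adjusted over the list alone). Foxo1 gave log2 -0.45 (adjusted p = 0.0605) and Il7r, the interleukin 7 receptor, 1.26 (adjusted p = 0.0737). That list had a median of -0.01, a mean of 0.22 and a positive camera direction (adjusted p = 0.0918, 0.0417 without Het A and 0.00442 without KO B). Its median turned positive in these 2 fits, at 0.0322 without Het A and 0.15 without KO B. Among 23 chemokine receptors and homing genes 0 passed (limma; 7 higher and 3 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). Ccr7 gave log2 0.59 (adjusted p = 0.0770) and Cxcr3 1.39 (adjusted p = 0.0991), with camera's adjusted p = 0.0649, or 0.00263 without Het B.

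Of all lists, the interferon gamma response had the most members past the test. Of 19 measured genes 11 rose, 0 fell and 8 did not pass, and 17 rose when adjusted over the list alone. Gbp2, an interferon-induced guanylate-binding protein, rose 4.78-fold, from 6306 ± 573 in Het to 30510 ± 6420 in KO (SD, n = 3; limma, adjusted p = 0.0191). Tap1 and Tap2, the peptide transporter of antigen presentation, rose 2.54-fold and 2.02-fold, and Psmb9, an immunoproteasome subunit, 1.82-fold, with adjusted p between 0.0247 and 0.0253. For Tap1 this was the brighter probe set, and a dim one gave log2 -0.05. The median log2 of the list was 0.88 (camera, adjusted p = 6.62e-16), with adjusted p = 0.298 with an estimated correlation. Of 27 type I interferon response genes Isg20 (3.63-fold, adjusted p = 0.0277) and Zbp1 (2.53-fold, adjusted p = 0.0377) rose and 25 did not pass (9 higher and 0 lower when adjusted over the list alone). Their median log2 was 0.68 (camera, adjusted p = 3.21e-07), with adjusted p = 0.379 with an estimated correlation, and 0.43 without Het B.

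Proliferation genes lay higher as a list with 0 single genes past the test. Of 47 measured members 45 had a positive difference. By limma 0 passed (27 higher and 0 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). Melk, a mitotic kinase, read 758 ± 348 in Het and 3200 ± 1370 in KO (SD, n = 3; log2 2.10, adjusted p = 0.116) and Ccne1, the gene of cyclin E1, gave log2 0.75 (adjusted p = 0.126). The median log2 was 1.42 (camera, adjusted p = 1.04e-11), with adjusted p = 0.419 with an estimated correlation, and it was 0.82 without Het A.

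In 2 signalling lists 1 gene each rose. Socs3, an inhibitor of cytokine signalling, was the 1 of 17 IL-2 and STAT5 response genes past the test, 3.87-fold higher (5535 ± 956 to 21380 ± 3530, SD, n = 3; limma, adjusted p = 0.0222; 4 genes higher and 0 lower when adjusted over the list alone). The list's median log2 was 0.55 (camera, adjusted p = 0.000161), with adjusted p = 0.298 with an estimated correlation. Cdkn1a, the gene of the cell cycle inhibitor p21, was the 1 of 21 apoptosis and p53 response genes that passed, 4.27-fold higher (adjusted p = 0.0369; 4 higher and 0 lower when adjusted over the list alone). That list's median log2 was 0.17 (camera, adjusted p = 0.00878), with adjusted p = 0.298 with an estimated correlation. Of 15 glycolysis genes 0 passed (limma; 4 higher and 1 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). The phosphofructokinase genes Pfkp and Pfkl gave log2 0.74 and 0.47 (adjusted p = 0.0930 and 0.122), and a dimmer Pfkl probe set gave -0.03. The glycolysis median was 0.30 (camera, adjusted p = 0.00112), with adjusted p = 0.397 with an estimated correlation. Of 16 cholesterol synthesis genes 0 passed (limma; 0 higher and 1 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). Dhcr7 gave log2 -0.43 (adjusted p = 0.161) and Mvk -0.21, with camera's adjusted p = 0.386, or 0.0221 without KO B.

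Reported targets of T cell microRNAs included both increases and a decrease. Of 45 measured genes Tbx21, Cdkn1a and Cebpb rose, Egr2 fell and 41 did not pass (19 higher and 4 lower when adjusted over the list alone). Tbx21, Cdkn1a and Egr2 also stand in the Th1, apoptosis and p53, and activation lists, and 3 genes in the proliferation list. The list test of the targets is therefore not separate from theirs. Cebpb, a transcription factor reported as a miR-155 target, rose 4.08-fold (1108 ± 114 to 4772 ± 2060, SD, n = 3; limma, adjusted p = 0.0429). The median log2 was 0.39 (camera, adjusted p = 1.54e-05), with adjusted p = 0.298 with an estimated correlation. In the Dicer and microRNA pathway 0 of 14 genes passed (limma; 4 higher and 0 lower at an unadjusted p under 0.05, 3 higher when adjusted over the list alone). Ago2, an Argonaute protein that binds microRNAs, read 8882 ± 539 in Het and 12580 ± 638 in KO (log2 0.50, adjusted p = 0.0568) on the probe set that stands for it, another Ago2 probe set rose from 1927 ± 127 to 3831 ± 384 (log2 0.99, adjusted p = 0.0253), and Tnrc6b gave log2 0.46 (adjusted p = 0.0803). This pathway's median log2 was 0.30 (camera, adjusted p = 0.0184), with adjusted p = 0.329 with an estimated correlation. It was 0.18 without Het B, and the call ended under a stricter filter on dim probe sets (adjusted p = 0.0530).

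Markers of other cell types were measured beside these groups. Het B and KO B stood above the other arrays of their own group for the B cell genes Ms4a1 and Cd79a, the CD8 genes Cd8a and Cd8b1, the NK receptor Klrd1 and the myeloid gene Lyz2. Ms4a1 read 37.4, 524 and 48.1 in Het and 122, 717 and 117 in KO. Of 12 B cell markers 0 passed (limma; 1 higher and 0 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). Cd22 gave log2 1.37 (adjusted p = 0.173) and Cd74 1.26 (adjusted p = 0.303). Ighm, an antibody heavy chain gene, gave log2 -0.55 (adjusted p = 0.409) on its brightest probe set, but 4 of its 8 probe sets rose, by a log2 of 4.26 to 6.84 (limma, largest adjusted p = 0.0263). Camera's adjusted p for the B cell markers was 0.248, or 0.00276 without Het B. Of 6 plasma cell markers Xbp1, a factor of secretory cells that was bright in Het too, rose from 7645 ± 341 to 14240 ± 1430 (SD, n = 3; log2 0.89, adjusted p = 0.0270) and 5 did not pass (3 higher and 0 lower when adjusted over the list alone). The plasma cell median log2 was 1.27 (camera, adjusted p = 0.0142), with adjusted p = 0.397 with an estimated correlation, and adjusted p = 0.0537 by camera without Het C. Mpeg1 was the 1 of 16 myeloid and dendritic cell markers past the test (1 higher and 0 lower when adjusted over the list alone), at 16.1, 89.7 and 52.9 in Het and 727, 1274 and 1212 in KO. Of the 16 markers 14 had a positive difference, with 4 higher and 0 lower at an unadjusted p under 0.05 (limma). Lyz2 read 50.6, 381 and 97.4 in Het and 232, 1408 and 441 in KO. The myeloid median log2 was 0.53 (camera, adjusted p = 0.000951), with adjusted p = 0.397 with an estimated correlation.

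The remaining marker lists gave 0 genes past the test by limma. The alpha beta T cell genes had 13 measured members (1 higher and 1 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone). Among these Cd2 gave log2 0.32 (adjusted p = 0.112) and Cd3d -0.23 (adjusted p = 0.200), with camera's adjusted p = 0.748. Of 7 stromal and endothelial genes 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Esam gave log2 0.18 and Col1a1 -0.11, the list's median was -0.02 and its mean 0.02, camera's direction was positive and fry's negative, and camera's adjusted p was 0.806. In 4 lists under 3 members were measured, so these had no list test, and 0 of their genes had an unadjusted p under 0.05 or passed when adjusted over the list alone. Cd8a and Cd8b1 gave log2 0.03 and 0.26, the NK gene Klre1 -0.08, the gamma delta T cell gene Sox13 -0.22, and the erythroid genes Car2 and Slc4a1 -0.39 and -0.00396 (0.31 on the other Slc4a1 probe set). The sign of Cd8a, Cd8b1 and Slc4a1 turned under other settings.

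**Figure D2:**
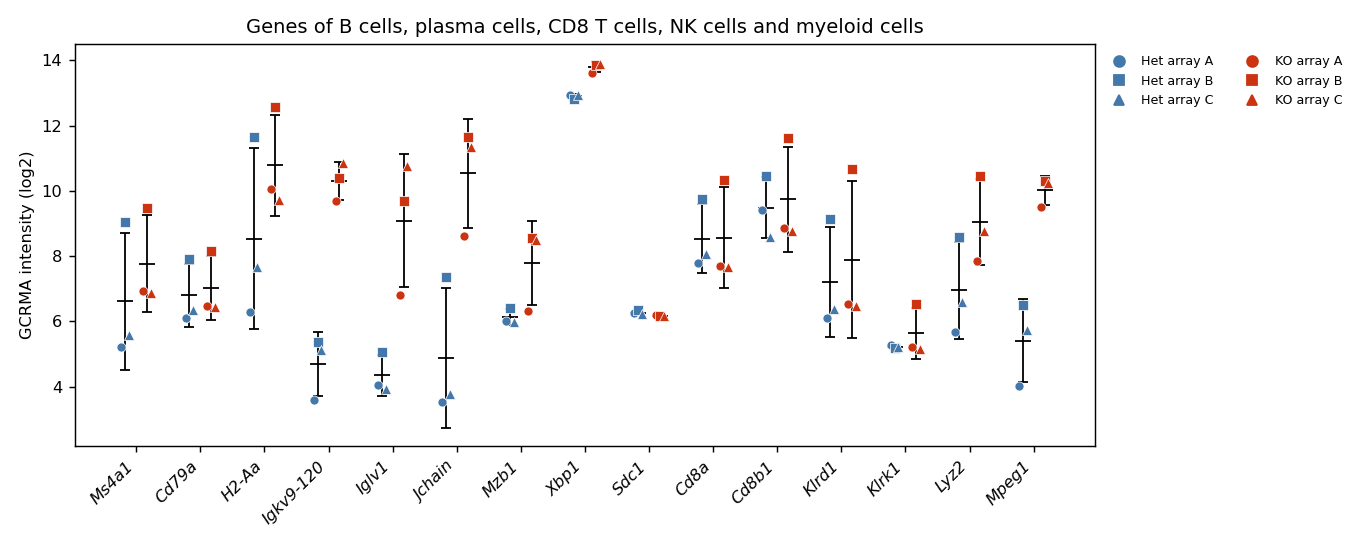
GCRMA intensity (log2, vertical axis) of 15 genes of other cell types on each of the 6 arrays. Points are arrays (Het blue, KO red, shape by letter), and bars are the mean ± SD of the 3 arrays of a group. Array B is the highest of its group for Ms4a1, Cd79a, H2-Aa, Cd8a, Cd8b1 and Klrd1 in both genotypes, while Igkv9-120, Iglv1, Jchain, Xbp1 and Mpeg1 lie higher on all 3 KO arrays than on any Het array.

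Across the 24 lists that were tested, 14 lay higher in KO than other genes and 0 lower by camera with its preset correlation (adjusted p under 0.05). With an estimated correlation 0 of the 14 calls held (smallest adjusted p = 0.298). For apoptosis and p53 genes that estimate was 0.017, near the preset 0.01, yet camera's adjusted p went from 0.00878 to 0.298. For reported microRNA targets it was 0.037, and the adjusted p went from 1.54e-05 to 0.298. Correlation between genes alone therefore does not account for the loss of these 2 calls. By fry, which asks whether the genes of a list move one way on balance, 5 lists passed: Th1 genes, the interferon gamma response, the IL-2 and STAT5 response, apoptosis and p53 genes, and reported microRNA targets. By fry's test for change in either direction, 20 lists passed.

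**Figure D3:**
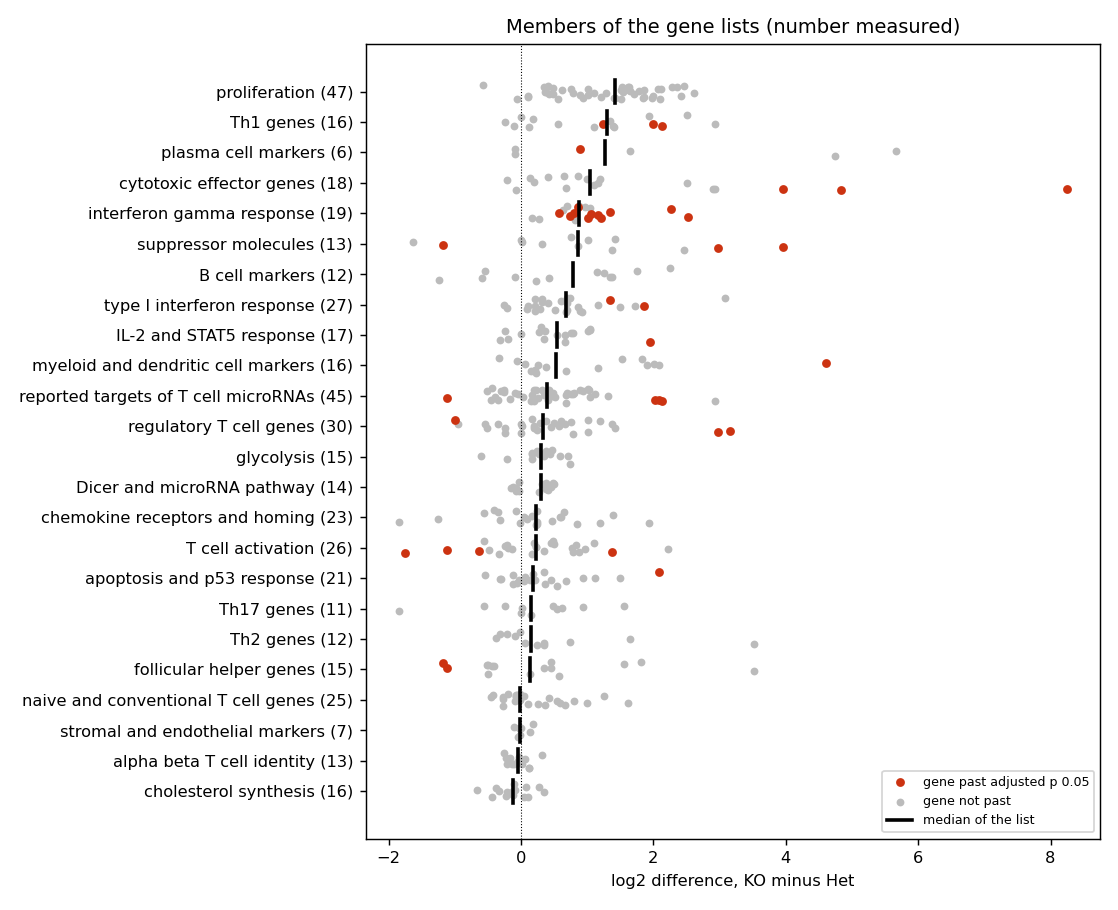
Log2 difference, KO minus Het (horizontal axis), of every measured member of the 24 lists tested, with the number of members in parentheses. Red points are genes past an adjusted p of 0.05, grey points are other genes, and black bars are list medians. The interferon gamma response has 11 of 19 members past the test, all higher in KO, and the proliferation list has the highest median (1.42) with 0 members past it.

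Genes near Dicer1 on chromosome 12 were counted, because DNA flanking the lox allele can come from another strain. Within 5 Mb either side, 4 of 62 measured genes changed (6.45%), against 305 of 13192 elsewhere (2.31%), an odds ratio of 2.91 (95% interval 0.763 to 7.95; Fisher's exact test, two-sided, p = 0.0564). The 4 genes, named because the count is small, were Asb2 (mean log2 intensity 7.91 in Het and 9.90 in KO), Wars (log2 difference 1.24), Itpk1 (1.17) and Rps6ka5 (0.98), all higher in KO. The dimmer Itpk1 probe set gave log2 0.03. Within 10 Mb the share was 3.28% (Fisher's exact test, p = 0.373), and within 2 Mb it was 6.9%, or 2 of 29 genes (odds ratio 3.12, p = 0.146).

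RNA quality was compared through the control probe sets. The log2 difference between the 3' and 5' probe sets of beta-actin was 0.77, 0.59 and 0.95 in Het and 0.50, 1.10 and 0.59 in KO (exact permutation test, two-sided, p = 0.9, n = 3 per group). For Gapdh it was 0.48 ± 0.09 in Het and 0.46 ± 0.19 in KO (SD, n = 3; exact permutation p = 0.8). Beside these ratios, the 3' probe set of 18S ribosomal RNA read 4702, 7119 and 2071 in Het and 9503, 805 and 6462 in KO (log2 values, exact permutation p = 0.9). KO B was thus the lowest array for 18S and the highest on both ratios. The smallest p that 3 arrays against 3 can give is 0.1, so none of these tests could pass.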

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

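Tests without both B arrays and with the beta-actin ratio as a covariate were chosen after the data were seen, the others before. The 525 changed probe sets became 0 with the replicate block (limma; 5365 at an unadjusted p under 0.05, smallest adjusted p = 0.0801), 957 with array weights, 306 with a log2 difference of at least 1, 0 to 176 when 1 array was left out, and 0 without both B arrays (smallest adjusted p = 0.137). The median absolute log2 difference of the 525 was 1.14 in the main comparison, 1.11 to 1.16 when 1 array was left out and 1.12 without both B arrays. Fewer arrays or residual degrees of freedom enter the block and left-out fits. Elsewhere the count was 415 without the filter, 721 with the stricter one, 496 with quantile normalization, 523 with median centring, 553 with trend and robust estimation and 560 with the covariate. Of the 525, 461 stayed called with quantile normalization, 470 with median centring and 373 with the covariate. The letters were not taken to pair the arrays, since the labels give no shared day or litter and deviations from the group means correlated by 0.28 for A, -0.17 for B and 0.01 for C, and Het C correlated best with KO B (0.37). Some genes do follow the letter: array B was the highest of both groups for Ms4a1 and Cd8a. With the replicate block 15 lists passed, the B cell markers among them (adjusted p = 0.0112). Of the 14 list calls, 0 held with an estimated correlation and 5 with fry, and the number of lists called was 13 to 17 when 1 array was left out and 13 to 19 under the other settings with the preset correlation. All 43 named genes past the threshold kept their direction with quantile normalization and median centring, and leaving out arrays could not turn it, since their groups do not overlap. Some values near 0 turned sign, and the cause was not tested. The median of the naive and conventional T cell genes went from -0.00802 to 0.154 without KO B. Dicer1 ranged from -0.0942 to 0.0262 when 1 array was left out, Cd8b1 from -0.68 to 0.75, Cd8a from -0.86 to 0.63 and Slc4a1 from -0.20 to 0.16. Cd8a was -0.00748 with quantile normalization, -0.18 with array weights and -0.26 without both B arrays, and Cd8b1 was -0.19 without both B arrays. Slc4a1 was 0.00439 with quantile normalization, 0.16 with the mean of its probe sets and 0.0163 with the covariate. Signal over background limits the folds of genes dim in one group. The planned microRNA seed test and its alternatives were not run.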

Other observations

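The tests of RNA quality and of other cell types below were chosen after the results were seen, and the count over other splits of the arrays was planned.

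Below the 10 largest changes, several further genes passed the threshold, and those named here were picked after their values were seen. Ifitm3 rose from 1237 in Het to 19380 in KO (log2 4.05 ± 0.33, SE; limma, adjusted p = 0.0191) and Ifitm2 by a log2 of 2.80, so with Ifitm1 there were 3 interferon-induced transmembrane genes among the 25 named increases of largest size. H2-DMa, which helps to load peptides onto MHC class II, rose by a log2 of 2.92, Adam9, a membrane metalloprotease, by 3.38, Ncf1, a subunit of the phagocyte NADPH oxidase, by 2.51 and Parp12 by 2.50. The B cell marker H2-Aa read 77.9, 3183 and 205 in Het and 1059, 6042 and 848 in KO. Whether other cells in the sort contributed to H2-DMa and Ncf1 was not tested. Id3, an inhibitor of E protein factors related to Id2, fell from 5429 to 1233 (log2 -2.13 ± 0.32, adjusted p = 0.0453), while Id2 rose. Ephx1, an epoxide hydrolase, fell from 9829 to 3548 (log2 -1.50), and Eno3, the muscle enolase (-1.97), and Tlr7, a sensor of single-stranded RNA (-1.51), were lower too.

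Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) called as many as 525 probe sets, and the highest of the others called 1. With 10 splits the share cannot fall below 0.05. RNA quality as the whole cause, as far as control ratios show it, is argued against: on 2 of 2 ratios (3' to 5', beta-actin and Gapdh) KO A lay below every Het array and KO B above, while each of the 525 has all KO arrays on one side of all Het arrays. The loss of Dicer stays open as a hypothesis, and the design does not separate it from anything else that differs between the samples of the 2 genotypes.

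Gzma, Gzmb and Gzmk lay above every Het array in all 3 KO arrays. CD8 T cells in the sort, which the CD4+YFP+ gate is meant to remove, are argued against as the whole cause: Cd8a and Cd8b1 both lay above every Het array in 1 of the 3 KO arrays (KO B), while KO C had the highest Gzma (20718) with Cd8a at 203. For NK cells in the sort, which the same gate is meant to remove, the genes did not decide. Klrd1 and Klrk1 both lay above every Het array in 1 of the 3 KO arrays (KO B). Klrk1 was dim, at 35.4 to 38.3 on the other arrays, so it tells little. Klrd1 read 91.8 and 89.0 in KO A and KO C, below Het B (566) but above Het A and Het C (69.2 and 83.1). Het B thus held more Klrd1 than KO A and KO C, with Gzma at 17.2 against 959 and 20718. An earlier count, which needed 2 of Klrd1, Nkg7 and Klrk1 to be bright and not raised, had found 1 (Klrd1) and decided nothing. Nkg7 and Eomes lay above every Het array in all 3 KO arrays, so NK cells, a part from CD8 T cells, and expression by the sorted cells themselves stay open.

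Of the antibody chain genes, 4 of 8 Ighm probe sets rose, Igkv9-120 rose from 29.4 ± 15.5 to 1341 ± 510 (SD, n = 3; limma, adjusted p = 0.0232) on its brighter probe set, and Jchain read 11.5, 163 and 13.6 in Het and 389, 3197 and 2623 in KO (log2 5.66, adjusted p = 0.10). The dimmer Igkv9-120 probe set gave log2 1.03 (limma, adjusted p = 0.22). B cells in the sort, which the CD4+YFP+ gate is meant to remove, are argued against as the whole source, since Ms4a1 and Cd79a lay above every Het array in 1 of the 3 KO arrays (KO B), and Het B held more Ms4a1 (524) than KO A or KO C with Igkv9-120 at 41.6. A part from B cells stays open, as Ms4a1 read 122 and 117 in KO A and KO C against 37.4 and 48.1 in Het A and Het C. For plasma cells in the sort, which that gate is meant to remove too, 1 of Sdc1, Derl3, Mzb1 and Xbp1 (Xbp1, which Het cells express at 7251 to 7859) lay above every Het array in each KO array. Mzb1 did so in KO B and KO C (379 and 357), so plasma cells or their free RNA may contribute and cannot be told apart from expression in the sorted cells.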
